A study of Mus musculus with 12 samples.

How the data were processed

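Total RNA of heart and skeletal muscle from 6-month-old mice was hybridised to 2-colour Agilent mouse arrays, with 1 wild-type (WT) and 1 mutant (KIKO) RNA on each array, per the labels. WT mice C3, C4 and C8 were paired with KIKO mice E6, E3 and E7. The same 3 pairs gave both tissues, and each pair was hybridised in both dye orientations, so that 12 arrays were used, 6 per tissue. Extraction used Trizol and labelling a linear amplification kit for small RNA amounts, per the labels' protocols.

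The array tables hold deposited intensities per spot, the mean pixel brightness of the spot and the median of its local background in the green (Cy3) and the red (Cy5) channel, per the file headers. They were made with Agilent Feature Extraction version A.7.5.1, per the file headers. The same tables hold a deposited log10 ratio of red over green, for which the software subtracted a spatially fitted background and normalised the dyes with LOWESS, per the file headers. Flags for saturation, for non-uniform or outlying spots and for signal well above background came from the same software, and these flag columns are other values, deposited as 0 or 1 per the file headers. A table of the whole series holds 1 deposited log2 ratio per spot and array. What was done to make it is not given in the sources used here. Set against the scanner values, its columns were log2 red over green with medians from -0.00894 to 0.00746. They had correlations from 0.992 to 1 across probes with the values computed here, which with the medians settled centring and direction. A correlation does not settle the scale. Slopes on loess ratios without background correction ran from 0.957 to 1.28, so the log2 scale holds only roughly. This table was used only as an alternative.

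From the mean signals and the local background, log2 ratios were computed with limma 3.58.1 in R 4.3.3 (normexp background correction with an offset of 50, then loess within each array with control spots at weight 0). Control spots and spots flagged as outliers were left out afterwards, saturated spots were kept, and the spots of a probe were averaged. Ratios were turned to KIKO over WT with the dyes in the labels. Both dye orientations of a pair were averaged to 1 replicate, which required both arrays, so that each tissue has 3 replicates. A probe was retained in a tissue when it was well above background on at least 4 of its 6 arrays in the KIKO or in the WT channel, and a gene was tested with at least 2 measured pairs, a detail set during the analysis. Of several retained probes of a gene, the one with the highest mean log2 intensity over the 12 arrays stood for it. Of 20868 probes, 13819 were named through an accession in the RefSeq table of assembly GRCm38.p6, 2155 through a current and 2545 through an older symbol in the array tables, and 80 kept the symbol of those tables. The other 2269 probes had no name and stayed as rows of their own. No genome coordinates are printed, since the array tables name no build.

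limma fitted the 6 pair means of both tissues together, with a coefficient per tissue, a shared variance per gene and no replicate block (4 residual degrees of freedom with complete values, 2.467 from the prior). Heart, skeletal muscle and the difference heart minus skeletal muscle were tested 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists written before the data were examined (36, of which 35 with at least 5 measured members were tested) were compared with all other genes by camera with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. camera with a correlation estimated from the residuals (negative estimates set to 0) and, for heart and skeletal muscle, fry were run beside it. Members were also counted with p adjusted over the list alone. The list of the PPAR gamma pathway names a pathway that the study itself named on these samples, and is not independent evidence. Errors are standard deviations (SD) over the pairs.

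The mice pair the samples across tissues, since both tissues came from the same animals. As a check, the deviations of a pair from the tissue means had correlations across genes between heart and skeletal muscle of -0.297, -0.219 and 0.107 for pairs C3-E6, C4-E3 and C8-E7, and the mouse pair as a random block had a consensus correlation of -0.103.

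Genes named in the text were chosen by a rule fixed before the data were examined. It takes up to 12 genes each way per tissue past the threshold with 1 sign in all 3 pairs or, where fewer than 5 pass, the 5 with the smallest p. It takes the 3 genes each way with the smallest p for the difference, up to 4 members of each called list, and the genes of the sex check. The markers Ucp1, Cidea, Adipoq, Fabp4, Elovl3, Fhl2, Pln, Tnni3, Tnnt1, Pvalb, Tnnt3 and Actn3 and the genes named as past the unadjusted threshold in both tissues were chosen after their values were seen. A gene that the rule also names and a list defined by it are not reported here. Predicted genes without a symbol were counted and not named. A gene saturated on every array of both genotypes has no fold.

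The steps were tested on simulated arrays with 200 changed genes per tissue, in 5 simulations each. With 16460 genes in heart, 54.9% of the genes changed by 0.5 on the log2 scale, 81.5% of those changed by 1 and 96.7% of those changed by 2 were recovered, and 5.13% of the calls were false. With 15623 genes in skeletal muscle the shares were 51.3%, 83.6% and 97.6%, with 5.72% false. For the difference, with 15351 genes, they were 39.2%, 71.7% and 94.7%, with 5.99% false. The simulated noise was independent between genes and pairs, which the real arrays did not follow. The correlation estimated from their residuals was 0.212 between interferon-stimulated genes and 0.492 between fast-fibre genes. In simulated heart, 5.31% of unchanged genes had an unadjusted limma p under 0.05. The real heart arrays gave 261 genes where chance gives 823, so the recovered shares need not hold for them. In heart, the interferon list moved by -0.2 was called in 5 of 5 simulations, and without it 0 lists were called. With independent noise, this does not measure how often camera calls a list falsely on the real arrays.

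Alternatives covered the background correction, the normalisation, the deposited log ratios, the filter on dim probes, the probes per gene, the fit (each tissue alone, mouse pair as a block, 12 arrays with a dye term, unpaired channels), each dye orientation alone and each mouse pair left out. Each array was on its own slide, so that slide as a block was not run. Figures were drawn with matplotlib 3.10.9, and tables were read with the R package data.table (1.17.8) and Python 3.11.15.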

Results

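Gene expression was compared between mutant mice labelled KIKO and wild-type (WT) mice at 6 months of age, in heart and in skeletal muscle. Each tissue had 3 mouse pairs (C3-E6, C4-E3 and C8-E7, WT mouse first), each measured on 2 dye-swapped 2-colour arrays and counted as 1 replicate. Median spot signals ran from 65.67 to 189.5 in Cy3 and from 76.88 to 156.8 in Cy5, beside median negative-control signals from 43.13 to 149.7 and from 47.72 to 83.45. Between 63.14% and 89.61% of probes were well above background in a channel. The highest share was in Cy3 on the heart array of C3-E6 with KIKO in Cy3. There 85.19% of negative-control spots had the same flag, so it hardly separates signal from control in that channel. After the filter on dim probes, 16460 genes or unnamed probes were tested in heart, 15623 in skeletal muscle and 15351 in both. The number of arrays limits the precision. No gene reported here checks the labels or the dye direction, so directions are those of the samples labelled KIKO.

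The arrays held the tissues that their labels name. Cardiac troponin Tnni3 had a mean log2 level of 14.73 on heart arrays and 8.35 on skeletal muscle arrays, and the fast-fibre myosin light chain Mylpf had 7.04 and 15.77. Skeletal muscle arrays of both genotypes also held fat transcripts. The brown fat uncoupling protein Ucp1 had a median log2 level of 13.89 there against 6.16 in heart, Cidea 14.62 against 10.59 and the adipokine Adipoq 11.57 against 6.12. The WT muscle sample C8 held heart transcripts: 9 heart-enriched genes had a median of 12.1% of their heart level in C8, against 1.05% in its partner E7. In the other pairs this share lay between 0.927% and 1.71%.

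The heart comparison asked which transcripts differ in KIKO heart. Genes of fast-twitch muscle fibres were lower in the samples labelled KIKO. Myosin heavy chain Myh4 was at 0.411 times the WT level (log2 -1.28 ± 0.60, n = 3), Mylpf at 0.558 times (-0.84 ± 0.41, n = 3), and the fast troponins Tnnc2 and Tnni2 at 0.58 and 0.551 times (-0.79 ± 0.39 and -0.86 ± 0.61, n = 3). These 4 fell when adjusted over the list alone (limma, adjusted p = 0.0158, 0.0158, 0.0197 and 0.0347), in all 3 pairs, and 0 of them passed over all genes. Of 16 measured fast-fibre genes, 13 were lower (median -0.24, camera adjusted p = 1.86e-07), and the call was lost with an estimated correlation (adjusted p = 0.297 with an estimated correlation). The fall depended on the probe for Myh1 and Myh2. Their probes in the list had -0.38 and -0.14 in heart, while second probes, also retained there, had 0.0166 and 0.0546. A second Mylpf probe, not well above background in enough arrays of either tissue, had -0.00547. Heart holds little of these transcripts (Myh4 at a log2 level of 7.34 there and 15.9 in skeletal muscle). Of 24 genes that skeletal muscle holds in excess, the 12 outside the fast-fibre list had medians in heart of -0.133, -0.137 and -0.0404 in C3-E6, C4-E3 and C8-E7. These 12 include the fat genes Ucp1, Cidea and Cidec, the lipid synthesis gene Fasn, and Pck1, which the adipocyte list also holds. Without pair C4-E3, 0 of the 4 passed (adjusted p = 0.0625, 0.073, 0.151 and 0.244), and without C3-E6 Tnnc2 and Tnni2 did not (adjusted p = 0.0547 and 0.136).

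Interferon-stimulated genes formed the list with the smallest p in heart by camera at the preset correlation, though not at an estimated correlation. Of 29 measured, 25 were lower, with a median of -0.09 (camera adjusted p = 6.87e-08; adjusted p = 0.115 with an estimated correlation), and their median was below 0 in each pair. The median of interferon-stimulated genes, heart, was -0.11, -0.057 and -0.081 without C3-E6, C4-E3 and C8-E7 (adjusted p = 1.2e-06, 0.000674 and 2.85e-05). The guanylate-binding protein Gbp3 had -0.47 ± 0.16 (n = 3), the signalling factor Irf9 -0.18 ± 0.08 (n = 3) and the ubiquitin-like Isg15 -0.21 ± 0.14 (n = 3), and 0 members passed adjusted over the list alone or over all genes. Immediate early genes, which respond fast to stimuli, were lower for 19 of 25 (median -0.09, camera adjusted p = 0.000162; adjusted p = 0.305 with an estimated correlation). Ier3 fell by 0.44 ± 0.12 (n = 3, limma adjusted p = 0.0381 adjusted over the list alone), the transcription factor Klf4 had -0.69 ± 0.25 (n = 3), Ccn1 -0.26 ± 0.13 (n = 3) and the orphan nuclear receptor Nr4a1 -0.84 ± 1.12 (n = 2). Without pair C4-E3 that list was not called (camera adjusted p = 0.267, median 0.018) and Ier3 did not pass (limma adjusted p = 0.144), nor did it without C8-E7 (adjusted p = 0.109).

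Citric acid cycle and glycolysis genes were higher as groups in KIKO heart by small amounts, while complex I, complex IV and ATP synthase lists were not called (medians -0.0188, -0.0239 and -0.0394). Citric acid cycle and pyruvate dehydrogenase genes were higher for 25 of 29 (median 0.08, camera adjusted p = 0.000892; adjusted p = 0.1 with an estimated correlation), among them the dehydrogenase subunits Dld (0.19 ± 0.06, n = 3) and Pdhx (0.21 ± 0.09, n = 3). On the same list, the cytosolic malate dehydrogenase Mdh1 had 0.28 ± 0.41 (n = 3) and the mitochondrial Mdh2 had -0.0721. Glycolysis and glycogen genes were higher for 25 of 31 (median 0.07, camera adjusted p = 0.00321; adjusted p = 0.449 with an estimated correlation), among them the lactate transporter Slc16a1 (0.27 ± 0.18, n = 3), the phosphofructokinase Pfkp (0.20 ± 0.15, n = 3) and Pgk1 (0.18 ± 0.08, n = 3). Both medians were below 0 in pair C8-E7 (-0.0263 and -0.0252). Without C3-E6 neither list was called (camera adjusted p = 0.0558 and 0.128), and without C4-E3 the glycolysis list was not (adjusted p = 0.105) and the median of the citric acid cycle, heart, was 0.04 (adjusted p = 0.035).

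The co-chaperone Dnajb1 fell to 0.726 times the WT level in heart (-0.46 ± 0.23, n = 3) adjusted over its list alone (limma, adjusted p = 0.0344). Slc25a4, the ADP/ATP carrier of the inner mitochondrial membrane, also passed over its list alone (adjusted p = 0.0392). It was saturated on 5 of 6 KIKO and 4 of 6 WT heart channels and had 0.13 with KIKO in Cy3 alone, so no fold is given. Neither gene passed over all genes, and with 1 pair left out Slc25a4 had adjusted p = 0.159, 0.106 and 0.272 without C3-E6, C4-E3 and C8-E7, and Dnajb1 0.0961, 0.172 and 0.0279. Other called lists in heart were small shifts. Brown adipocyte genes were lower for 9 of 9 (median -0.08, camera adjusted p = 0.0221; adjusted p = 0.0918 with an estimated correlation), with Ppargc1a at -0.28 ± 0.30 (n = 3) and Dio2 at -0.11 ± 0.14 (n = 3). Smooth muscle and pericyte genes were higher for 10 of 11 (median 0.10, adjusted p = 0.0249; adjusted p = 0.305 with an estimated correlation), with Tagln at 0.33 ± 0.43 (n = 2). Without C3-E6 neither list was called (camera adjusted p = 0.147 and 0.267), nor without C4-E3 the smooth muscle list (adjusted p = 0.267). The brown adipocyte list was also not called with median centring, with no filter on dim probes or with KIKO in either dye alone. The smooth muscle list also lost its call with only KIKO in Cy5 and with negative-control background, among others.

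Over all genes, limma called 0 in heart at an adjusted p of 0.05 (smallest adjusted p 0.9997). At an unadjusted p under 0.05, 114 were higher and 147 lower, 261 in all, against 823 that chance gives. Over the lists, 0 members were higher and 7 lower when adjusted over the list alone. camera called 8 of 35 lists, 0 with an estimated correlation, and fry called 0. Of the genes with the smallest p, the higher ones were the tRNA deaminase subunit Adat2 (0.37 ± 0.13), the chromatin protein Rbbp4 (0.62 ± 0.38), the heme synthesis enzyme Alas1 (0.38 ± 0.10), the membrane junction protein Jph2 (0.22 ± 0.08) and Tmem143 (0.26 ± 0.14), all n = 3. The keratin Krt18 had -0.31 ± 0.02 (n = 3). None of them passed the test.

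**Figure D1:**
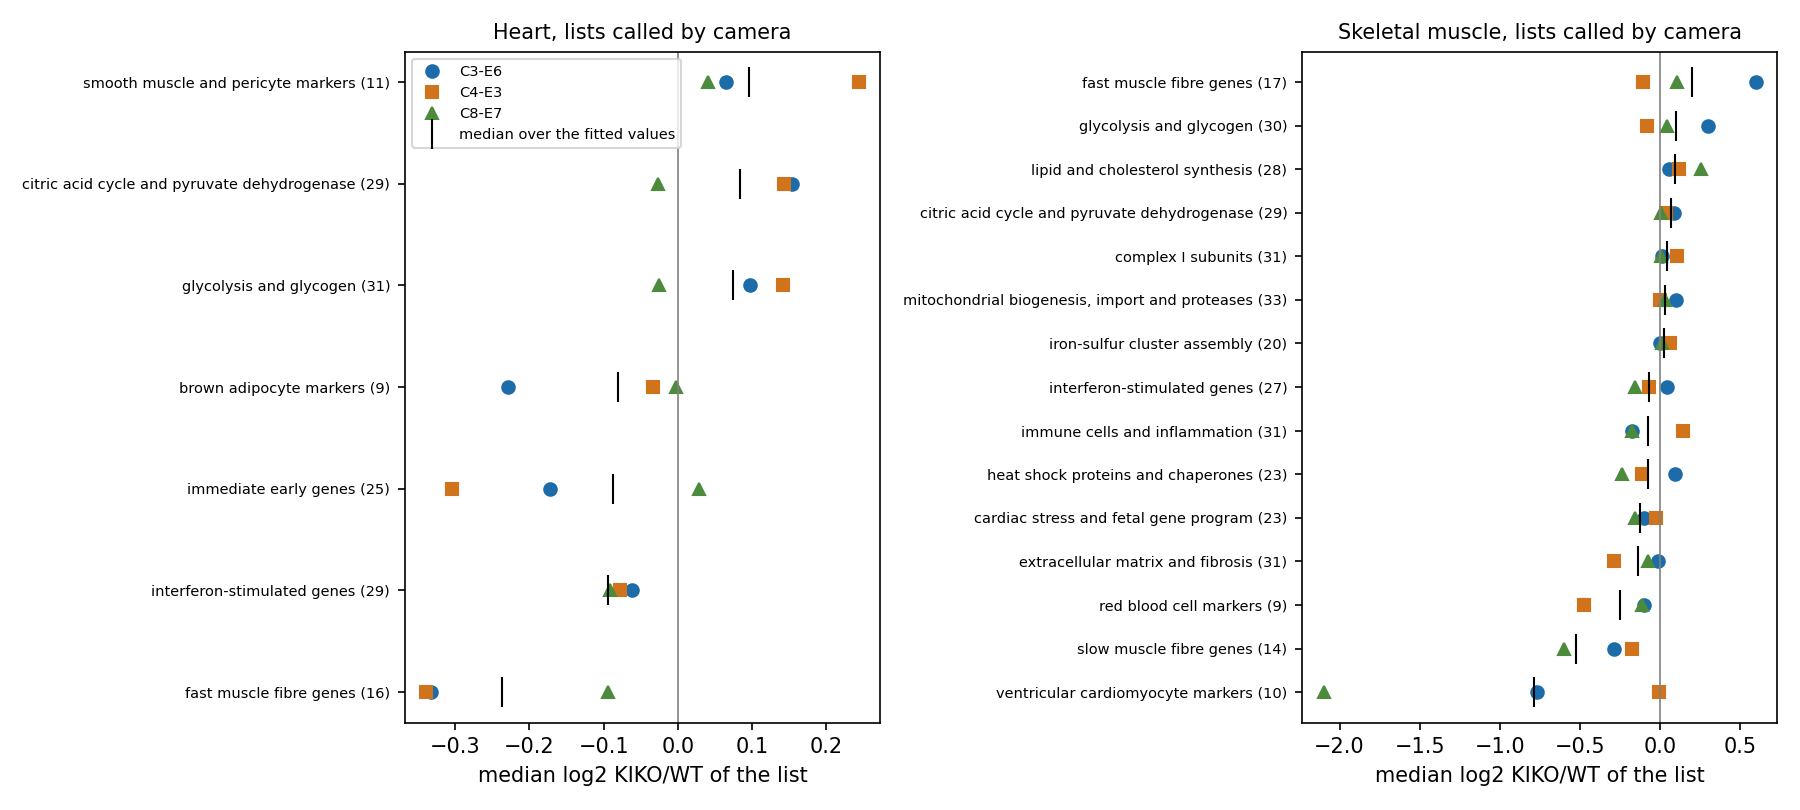
Median log2 KIKO/WT of each reported list called by camera in heart (left) and skeletal muscle (right), with the number of measured members in brackets, 1 symbol per mouse pair and a bar for the median of the fitted values. The heart interferon list lies below 0 in all 3 pairs. The medians of fast-fibre genes in skeletal muscle run from -0.106 to 0.599, which are values of the saturated gene Tnnc2.

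In skeletal muscle, lipid synthesis was the list with the smallest p by camera at the preset correlation. ATP citrate lyase Acly, which makes cytosolic acetyl-CoA, was 1.92 times as high in the samples labelled KIKO (0.94 ± 0.29, n = 3), as was the desaturase Scd2 (0.94 ± 0.43, n = 3), the malic enzyme Me1, a source of NADPH, was 1.45 times as high (0.54 ± 0.11, n = 3) and fatty acid synthase Fasn 1.38 times (0.46 ± 0.12, n = 3). All 4 rose in each pair when adjusted over the list alone (limma, adjusted p = 0.000958 for Acly and Me1 and 0.00467 for Scd2 and Fasn). Of 28 measured lipid and cholesterol synthesis genes, 24 were higher (median 0.10, camera adjusted p = 9.7e-12; adjusted p = 0.000183 with an estimated correlation). The median of lipid synthesis, skeletal muscle, was 0.21, 0.16 and 0.048 without C3-E6, C4-E3 and C8-E7, and the list was called each time. Over all genes none of the 4 passed (adjusted p = 0.267 for Acly and Me1, 0.869 for Scd2 and Fasn), and without pair C8-E7 Fasn missed the test over the list alone (adjusted p = 0.0561). A second Me1 probe had 0.67, and Fasn was saturated on 2 of 6 channels of each genotype.

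Acot11, an acyl-CoA thioesterase that is induced by cold in brown fat, was 1.61 times as high (0.69 ± 0.06, n = 3, limma adjusted p = 0.267), while its second probe, not well above background in enough muscle arrays, had -0.01. The fatty acid elongase Elovl3, counted among brown adipocyte genes, rose by 0.74 ± 0.23 (n = 3) adjusted over that list alone (limma, adjusted p = 0.0147), but not without C8-E7 (adjusted p = 0.0794). The brown adipocyte list as a whole was not called (11 measured, median -0.14, mean 0.00259, camera adjusted p = 0.844). Ucp1 had -0.57, 0.11 and 0.47 and Cidea -0.65, 0.15 and 0.05 in C3-E6, C4-E3 and C8-E7, where Acly, Me1, Scd2 and Fasn averaged 0.67, 0.57 and 0.93. White adipocyte markers were not called (12 measured, median -0.06, camera adjusted p = 0.433).

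**Figure D2:**
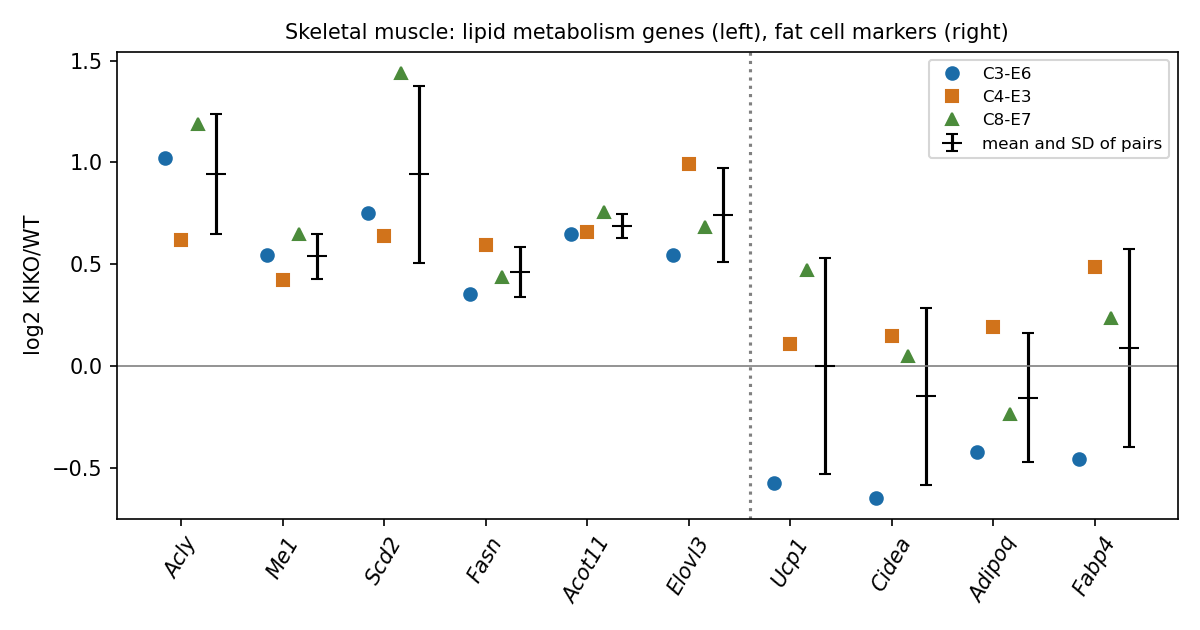
Log2 KIKO/WT in skeletal muscle for 6 lipid metabolism genes (left) and 4 fat cell markers (right), with 1 symbol per mouse pair and the mean and SD of the 3 pairs. The 6 genes are above 0 in every pair, while Ucp1, Cidea, Adipoq and Fabp4 lie below 0 in C3-E6 and above 0 in C4-E3. Of markers not drawn, Cfd (-0.547) and Plin1 (-0.0531) were below 0 in C4-E3, where the white adipocyte list had a median of 0.074.

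Slow-fibre genes were lower in KIKO muscle as a list, with different members falling in different pairs. Of 14 measured, 12 were lower with a median of -0.53 (camera adjusted p = 0.000145; adjusted p = 0.000183 with an estimated correlation). The myosin light chains Myl3 and Myl2, shared by slow fibres and heart ventricle, had -1.08 ± 0.97 and -0.94 ± 1.08, the slow troponin Tnni1 -0.42 ± 0.41 and Tnnc1, shared with heart, -0.52 ± 0.44 (n = 3 each), and 0 members passed adjusted over the list alone. A second Myl3 probe had -0.41. Ventricular cardiomyocyte genes were lower for 10 of 10 (median -0.79, camera adjusted p = 9.04e-05; adjusted p = 0.0548 with an estimated correlation), with Mybpc3 at -1.84 ± 3.17 (n = 3) and Tnnt2 at -1.75 ± 2.91 (n = 3). Genes of the cardiac stress program were lower for 20 of 23 (median -0.12, adjusted p = 0.012; adjusted p = 0.0215 with an estimated correlation), with the repair protein Xirp1 at -0.39 ± 0.28 (n = 3), the calcium pump Atp2a2 at -0.83 ± 0.74 (n = 3) and Acta1 at 0.24 ± 0.12 (n = 3). Without C8-E7, whose WT muscle held heart transcripts, the ventricular list had a median of -0.29 (camera adjusted p = 0.0704), the stress list -0.10 (adjusted p = 0.141) and the slow-fibre list -0.36 (adjusted p = 0.00213). Heart-enriched genes and the slow-fibre list were both lower in C3-E6 (medians -1.02 and -0.288) and C8-E7 (-4.24 and -0.601), and parted in C4-E3 (0.562 and -0.173). The median of slow muscle fibre genes, skeletal muscle, was -0.68 without C3-E6 and -0.28 without C4-E3 (camera adjusted p = 1.13e-06 and 0.00333). Tnni1 and Tnnt1, of which heart holds little, had -0.39 and -0.21 in C3-E6, -0.84 and -1.31 in C4-E3 and -0.02 and -0.07 in C8-E7. They fell most in C4-E3, whose dye-swapped muscle arrays had a correlation of -0.201 across bright probes. Myl3 and Myl2 fell most in C8-E7 (-2.17 and -2.1).

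**Figure D3:**
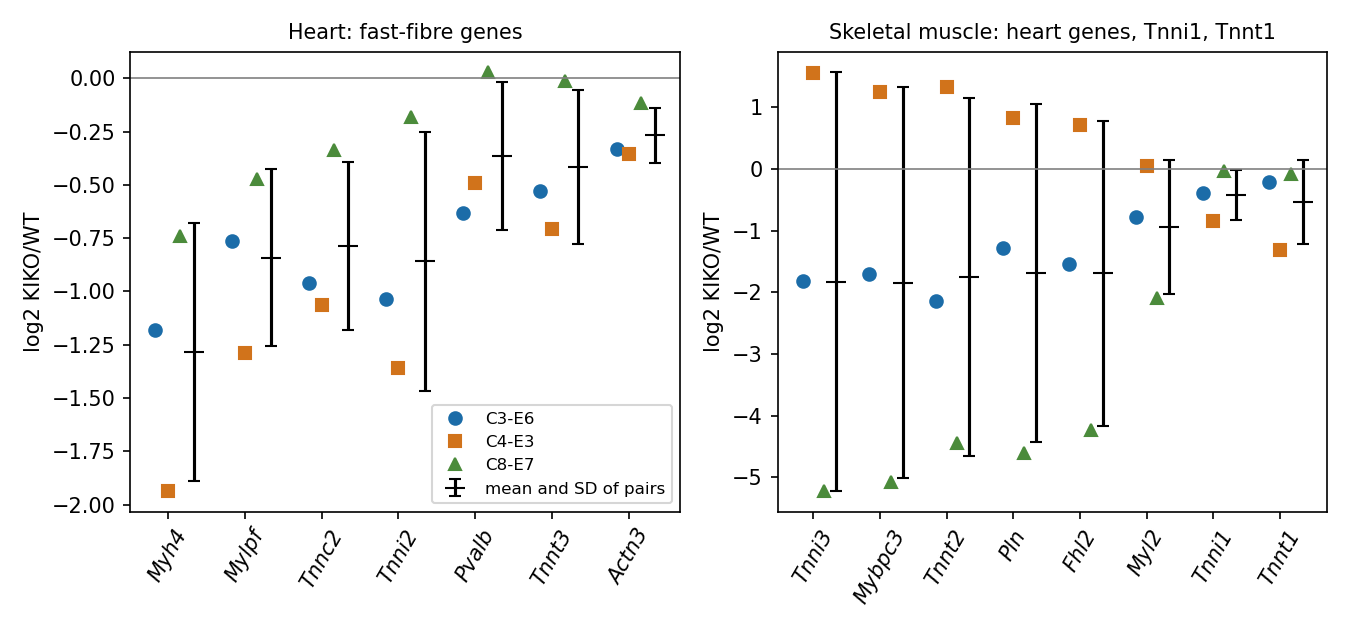
Log2 KIKO/WT of 7 fast-fibre genes in heart (left) and of 6 heart genes with the slow-fibre troponins Tnni1 and Tnnt1 in skeletal muscle (right), with 1 symbol per mouse pair and the mean and SD of the pairs measured. Tnni3 in skeletal muscle had -5.22 in C8-E7 and 1.57 in C4-E3, while Tnni1 had -0.02 in C8-E7.

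Other groups also shifted in KIKO muscle. Dnajb1 fell to 0.553 times the WT level (-0.85 ± 0.05, n = 3, limma adjusted p = 0.00102 adjusted over the list alone, and 0.267 over all genes). Chaperones as a list were lower for 16 of 23 (median -0.07, camera adjusted p = 0.00302; adjusted p = 0.0548 with an estimated correlation), with Dnaja1 at -0.41 ± 0.14 and Hsp90aa1 at -0.51 ± 0.29 (n = 3 each). Red blood cell genes were lower for 8 of 9 (median -0.25, adjusted p = 4.06e-05; adjusted p = 0.0548 with an estimated correlation), with the globin Hbb-bt at 0.367 times (-1.45 ± 0.56, n = 3) and the erythroid heme enzyme Alas2 at -0.84 ± 0.42 (n = 3). Extracellular matrix genes were lower for 28 of 31 (median -0.14, adjusted p = 4.06e-05; adjusted p = 0.0984 with an estimated correlation), with the collagen Col3a1 at -0.46 ± 0.17 (n = 3) and Sparc at -0.41 ± 0.09 (n = 2). Interferon-stimulated genes were lower for 26 of 27 (median -0.07, adjusted p = 0.000292; adjusted p = 0.214 with an estimated correlation), with Gbp3 at -0.36 ± 0.22 and the antigen-presentation protein B2m at -0.26 ± 0.16 (n = 3 each). Immune cell genes were lower for 25 of 31 (median -0.07, adjusted p = 0.0168; adjusted p = 0.613 with an estimated correlation), with the protease Ctss at -0.38 ± 0.52 (n = 3) and the chemokine Ccl2 at 0.33 ± 0.47 (n = 3). Without C4-E3 the median of red blood cell genes, skeletal muscle, was -0.12 (adjusted p = 0.0276), and the matrix list (adjusted p = 0.724) and the interferon list (adjusted p = 0.0692) were not called. Without C8-E7 the chaperones (adjusted p = 0.312), the interferon list (adjusted p = 0.347) and the immune list (adjusted p = 0.889) were not, and the immune list was also not called without C3-E6 (adjusted p = 0.739).

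Glycolysis genes in muscle were higher for 23 of 30 (median 0.10, camera adjusted p = 4.06e-05; adjusted p = 0.0984 with an estimated correlation), with the phosphofructokinases Pfkl (0.45 ± 0.38, n = 3) and Pfkp (0.25 ± 0.15, n = 3). Fast-fibre genes were higher for 13 of 17 (median 0.20, camera adjusted p = 0.000145, and 0.285 with an estimated correlation), with Myh2 at 0.46 ± 0.55 (n = 3). The Myh2 probe was saturated on 1 of 6 channels of each genotype, and a second Myh2 probe had 0.18. Mylpf was saturated on 4 of 6 channels of each genotype, so no fold is given. Tnnc2 and Tnni2 were saturated on all 6 channels of both genotypes. Both lists rest on pair C3-E6, where their medians were 0.3 and 0.599. Without it they were -0.019 (camera adjusted p = 0.915) and 0.0016 (adjusted p = 0.777). The fast-fibre medians, 0.20 in all and 0.599, -0.106 and 0.108 in C3-E6, C4-E3 and C8-E7, equal the values of the saturated Tnnc2. Their size is therefore not a measured fold.

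In muscle, 4 mitochondrial lists were called higher, by small amounts, and the others were not called. Complex I subunits were higher for 26 of 31 (median 0.05, camera adjusted p = 0.00188; adjusted p = 0.0548 with an estimated correlation), with Ndufa12 at 0.20 ± 0.18 (n = 3). Mitochondrial biogenesis, import and protease genes were higher for 24 of 33 (median 0.03, adjusted p = 0.00573; adjusted p = 0.231 with an estimated correlation), with the outer membrane channel Vdac1 at 0.36 ± 0.16 (n = 3) and the protease Clpp at 0.25 ± 0.23 (n = 3). Citric acid cycle genes were higher for 21 of 29 (median 0.07, adjusted p = 0.012; adjusted p = 0.126 with an estimated correlation), with the pyruvate dehydrogenase subunit Pdha1 at 0.19 ± 0.11 (n = 3). Genes of iron-sulfur cluster assembly, which builds the cofactors of respiratory enzymes, were higher for 14 of 20 (median 0.03, adjusted p = 0.0347; adjusted p = 0.0548 with an estimated correlation), with the scaffold protein Iscu at 0.26 ± 0.20 (n = 3) and Isca1 at 0.15 ± 0.07 (n = 3). With median centring in place of loess all 4 medians turned, to -0.027, -0.024, -0.0081 and -0.041 in this order, and with only KIKO in Cy3 to -0.025, -0.019, -0.049 and -9.8e-05. Without C4-E3 complex I (adjusted p = 0.522), the citric acid cycle (adjusted p = 0.178) and cluster assembly (adjusted p = 0.588) were not called, and without C3-E6 neither were biogenesis (adjusted p = 0.739), the citric acid cycle (adjusted p = 0.235) and cluster assembly (adjusted p = 0.117). Without C8-E7 cluster assembly had adjusted p = 0.0892.

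Over all genes, limma called 0 in skeletal muscle (smallest adjusted p 0.2672). At an unadjusted p under 0.05, 232 were higher and 228 lower, 460 in all, against 781 that chance gives. This count was 1043 without pair C4-E3, whose dye-swapped muscle arrays had a correlation of -0.201 with each other across bright probes. Whether the dyes and labels of these arrays are as given was not tested, and the muscle values of C4-E3 rest on them. A fit of the 12 single arrays with a dye term called 4 genes, 3 higher (Acot11, Acly and Scd2) and 1 lower (Dnajb1). Over the lists, 5 members were higher and 1 lower when adjusted over the list alone. camera called 15 of 35 lists, 3 with an estimated correlation, and fry called 0. Further genes with the smallest p were the pattern-recognition protein Ptx3 (0.45 ± 0.08), the ISG15-conjugating enzyme Ube2l6 (-0.33 ± 0.05), the carboxypeptidase Scpep1 (-0.28 ± 0.07), the mitochondrial carrier Slc25a25 (-0.77 ± 0.41) and the platelet integrin Itga2b (-0.36 ± 0.12), all n = 3 and none past the test.

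Whether the effect of the genotype differs between tissues was tested as heart minus skeletal muscle. Lipid synthesis genes differed: 19 of 27 were lower on this scale (median -0.16, camera adjusted p = 2.79e-08; adjusted p = 0.00833 with an estimated correlation). The median of lipid synthesis, difference, was -0.26, -0.16 and -0.06 without C3-E6, C4-E3 and C8-E7. Acly differed by -0.97 (SE 0.15, n = 3 pairs per tissue) and Me1 by -0.51 (SE 0.08), both past the test adjusted over the list alone (limma, adjusted p = 0.00925), and their own values in heart were -0.03 and 0.02. The Acly probe was dim in heart, at log2 levels of 6.44 (KIKO) and 6.47 (WT) against 9.08 and 8.14 in muscle. It was well above background there on 5 of 6 heart arrays for each genotype. With 1 pair left out, Acly passed without C4-E3 (adjusted p = 0.00658) and not without C3-E6 (0.0601) or C8-E7 (0.0674), and Me1 likewise (0.0456, 0.0601 and 0.122). Fast-fibre genes were lower for 14 of 16 (median -0.44, camera adjusted p = 3.32e-10; adjusted p = 0.178 with an estimated correlation). The median of fast muscle fibre genes, difference, was -0.11, -0.70 and -0.71 without C3-E6, C4-E3 and C8-E7, and -0.21 with saturated genes left out. Mylpf, Tnnc2, Myh4 and Slc25a4 passed the same test over their lists alone, but spots of each were saturated, so no difference is given. None of them passed without C3-E6 (adjusted p = 0.18, 0.199, 0.199 and 0.275) or without C4-E3 (0.0563, 0.113, 0.0563 and 0.103), nor Slc25a4 without C8-E7 (0.322).

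The other called lists differed between tissues by camera. Extracellular matrix genes were higher on this scale for 23 of 30 (median 0.15, adjusted p = 0.0015; adjusted p = 0.314 with an estimated correlation), red blood cell genes for 9 of 9 (0.17, adjusted p = 0.0015; adjusted p = 0.272 with an estimated correlation) and ventricular genes for 10 of 10 (0.68, adjusted p = 0.00216; adjusted p = 0.272 with an estimated correlation). Smooth muscle genes were higher for 9 of 11 (0.14, adjusted p = 0.0345; adjusted p = 0.285 with an estimated correlation), and complex I subunits lower for 21 of 31 (-0.05, adjusted p = 0.0436; adjusted p = 0.285 with an estimated correlation). The complex I median turned to 0.23 with median centring (camera adjusted p = 0.0393). The call of this list was lost in 13 and reversed in 1 of 22 alternatives. Without C4-E3 the matrix, red blood cell, smooth muscle and complex I lists were not called (adjusted p = 0.952, 0.312, 0.437 and 0.896), without C8-E7 the ventricular and smooth muscle lists (0.341 and 0.0723), and without C3-E6 the ventricular and complex I lists (0.0564 and 0.263).

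Over all genes limma called 0 for the difference (smallest adjusted p 0.9996), with 281 at an unadjusted p under 0.05 against 768 by chance. Over the lists, 0 members were higher and 6 lower when adjusted over the list alone. camera called 7 of 35 lists, and 1 with an estimated correlation. The genes with the smallest p were the proton pump subunit Atp6v0a1 (0.43, SE 0.10), the forkhead factor Foxq1 (0.68, SE 0.14), the steroid sulfatase Sts (0.62, SE 0.15) and Ptx3 (-0.42, SE 0.08), beside Acly and Me1, and none passed the test. In heart, Ptx3 was well above background on 5 of 6 arrays for KIKO and 2 of 6 for WT.

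Across the 15351 genes measured in both tissues, the log2 fold changes of heart and skeletal muscle had a Pearson correlation of 0.171 and a Spearman correlation of 0.162, and 54.6% had the same sign. The Pearson correlation turned to -0.2 with median centring and to -0.15 without C3-E6. Genes are not independent replicates. The mean correlation between tissues was -0.0687 within a mouse pair and 0.0829 between different pairs, and between pairs of 1 tissue it was -0.0922. At an unadjusted p under 0.05 in each tissue, 6 genes were higher in both, against 1.62 for independent lists, and 14 lower in both, against 2.14. Another 6 were opposite, for which the value for independent lists was not computed. The fit gave both tissues 1 shared variance per gene, so a gene with a small variance gets a small p in both. The lists are therefore not independent, and the excess alone cannot show a shared effect. Adat2 (0.37 in heart, 0.48 in muscle), Acot11 (0.19, 0.69), Pfkp (0.20, 0.25) and Vdac1 (0.27, 0.36) were among the higher ones. Dnajb1 (-0.46, -0.85), Klf4 (-0.69, -0.69), Gbp3 (-0.47, -0.36), the gluconeogenic enzyme Pck1 (-0.26, -0.25) and the water channel Aqp1 (-0.28, -0.19) were among the lower ones.

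Lists of iron and mitochondrial function were mostly not called. Medians in heart were 0.01 for iron-sulfur cluster assembly (20 genes, camera adjusted p = 0.559), 0.02 for mitochondrial iron-sulfur proteins (17 genes, adjusted p = 0.559), -0.01 for iron uptake, storage and export (20 genes, adjusted p = 0.879) and 0.00117 for heme synthesis and breakdown (17 genes, adjusted p = 0.879). In skeletal muscle the last 3 had medians of 0.02 (adjusted p = 0.606), -0.03 (adjusted p = 0.811) and -0.00241 (adjusted p = 0.562). Respiratory chain lists in heart had medians of -0.02 for complex I (adjusted p = 0.559), 0.04 for complexes II and III (0.622), -0.02 for complex IV (0.646) and -0.04 for ATP synthase (0.462), and in muscle the last 3 had 0.05 (0.0775), -0.01 (0.318) and 0.04 (0.318). Fatty acid oxidation genes had medians of 0.06 in heart (adjusted p = 0.133) and -0.03 in muscle (0.418). The PPAR gamma and adipocyte list, which the study named on these samples and which is not independent evidence, had -0.02 in heart (0.765) and -0.10 in muscle (0.131), with 20 and 21 of 30 members lower and 0 past the test over the list alone or over all genes. Antioxidant and NRF2 targets had -0.00215 (0.882) and 0.04 (0.0588), and ATF4 stress genes -0.02 (0.543) and -0.03 (0.844).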

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

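The tests of explanations for the 3 patterns weighed were chosen after the results were seen, while the counts of sample splits and the tests of the difference between tissues were planned.

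In 152 groups of 6 array values, 6 groups held a single array far from the other 5, where chance gives 8. In heart these were the succinate dehydrogenase subunit Sdha, at a log2 KIKO/WT of 0.805 on the array of C3-E6 with KIKO in Cy5 (nearest other array 0.169), and the proton channel Otop1, at -1.03 on the array of C8-E7 with KIKO in Cy3 (nearest -0.156). The share of probes well above background in Cy3 was 73.8% on the heart array of C3-E6 with KIKO in Cy5 (nearest 84.1%). In skeletal muscle they were the pyruvate carboxylase Pcx, at 0.356 on the array of C4-E3 with KIKO in Cy3 (nearest -0.108), and the macrophage marker Adgre1, at 0.209 on the array of C4-E3 with KIKO in Cy5 (nearest -0.132). The share of negative controls well above background in Cy5 was 11.1% on the muscle array of C8-E7 with KIKO in Cy3 (nearest 3.09%).

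The effect in heart minus the effect in skeletal muscle differed from other genes for 7 lists by camera. Medians were -0.438 for fast-fibre genes (adjusted p = 3.32e-10), -0.16 for lipid synthesis (2.79e-08), 0.148 for extracellular matrix (0.0015), 0.172 for red blood cell genes (0.0015), 0.678 for ventricular genes (0.00216), 0.145 for smooth muscle genes (0.0345) and -0.0532 for complex I (0.0436). With an estimated correlation, only the lipid synthesis list of these 7 was called (adjusted p = 0.00833). The splits of the 6 pair values into 3 and 3 are too few for a share under 0.05, and they ignore that the same mice gave both tissues. Of 10 splits, 5 called as many lists as the real 7, with 13 the highest other, and 10 gave as many genes at an unadjusted p under 0.05 as the real 281, with 1145 the highest other.

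The heart transcripts in the WT muscle sample C8 were the first pattern weighed. In skeletal muscle of C8-E7, 9 of 9 heart-enriched genes were lower in KIKO, with a median log2 KIKO/WT of -4.24, against -1.02 in C3-E6 and 0.562 in C4-E3. Fewer slow fibres in E7 are argued against by Tnni1 and Tnnt1, slow-fibre genes of which heart holds little, with a mean of -0.0481 in this pair. Heart tissue or heart RNA in C8 stays open as a candidate explanation, and how it came there was not tested. It bears on the ventricular list, which was not called without C8-E7 (adjusted p = 0.0704), while the slow-fibre list was (adjusted p = 0.00213), though it moved with the heart-enriched genes in C3-E6 too.

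The lower fast-fibre genes in KIKO heart were the second pattern weighed. Genes held in excess by skeletal muscle, without the members of that list, had medians of -0.133, -0.137 and -0.0404 in C3-E6, C4-E3 and C8-E7. Traces of skeletal muscle in the WT heart samples cannot be told apart from lower expression in the heart itself, since these medians lie below 0 but less far than the test of such traces asked. The set also holds the fat genes Ucp1, Cidea and Cidec, which do not report fibre traces, and Fasn and Pck1, which need not. The distance of its medians from 0 therefore decides nothing. The day of image extraction, when Feature Extraction read the scans, was weighed too. The list was called lower without each of the 3 heart days in turn, with 3.48e-05 the highest camera adjusted p at the preset correlation. Each heart pair had its own day, so this equals leaving out each pair, and no single pair carries that call. Both genotypes were read together on each array, so the test decides nothing about the day itself. Days of RNA extraction, labelling or hybridisation were not weighed. The sign splits of 3 pairs are too few for a share under 0.05: of 4 splits, 2 called as many lists as the real 8 (highest other 10), and 3 gave as many genes at an unadjusted p under 0.05 as the real 261 (highest other 628).

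The higher lipid synthesis genes in KIKO muscle were the third pattern weighed. More white fat is argued against in C3-E6 and C8-E7, where the upper quartiles of white adipocyte markers (-0.0685 and 0.179) lay below the list's medians (0.0568 and 0.254), but not in C4-E3 (0.282 against 0.117). More brown fat is argued against in C3-E6, where the higher of Ucp1 and Cidea had -0.572, and stays open in C4-E3 and C8-E7. In C4-E3 they had 0.108 and 0.147, around the list's median though below Acly, Me1, Scd2 and Fasn (lowest 0.422), and in C8-E7 0.471 and 0.0522. Dye bias is argued against by the list, called higher with KIKO in each dye alone (higher camera adjusted p = 0.000582). C3-E6, the pair of day 3 of image extraction, is argued against as the only source. The list was also called among the pairs of day 2 alone (camera adjusted p = 1.47e-12). The pairs of day 2 as the only source stay open, since the lower quartile of the list in C3-E6 was -0.108. Both genotypes were read together on each array, so these values decide nothing about the day itself. A candidate explanation that stays open is higher lipid synthesis in KIKO muscle or in the fat cells within it, and which cells carry the change was not tested. The sign splits are again too few for a share under 0.05: of 4 splits, 1 called as many lists as the real 15 (highest other 11), and 4 gave as many genes at an unadjusted p under 0.05 as the real 460. The highest other, 2228, came with pair C4-E3 turned, several times the real count, which points to a structure of the samples in which C4-E3 stands against the other pairs.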

How the results depend on the processing

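Alternatives chosen after seeing the data were the day of image extraction as a block, a filter at the negative controls and outlier spots kept. So were negative-control background, the discordant muscle array left out and saturated genes left out. The other 21 of 27 were planned.

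For heart KIKO against WT, skeletal muscle KIKO against WT and the heart effect against the skeletal muscle effect, limma called 0 genes under each alternative but 1. The fit of 12 arrays with a dye term called 4 muscle genes. At an unadjusted p below 0.05 the counts were 261, 460 and 281, and at an unadjusted p below 0.005 they were 12, 40 and 15, the looser threshold being the cause. With the mouse pair as a random block 0 genes were called as before, and the unadjusted counts were 261, 458 and 225. The unadjusted muscle count was 559, 1043 and 333 without C3-E6, C4-E3 and C8-E7, and 1923 without the muscle array of C4-E3 with KIKO in Cy3. Slide as a block was not run.

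The number of gene lists called in heart was 8. It was 15 with median centring, 4 with negative-control background, 0 with an estimated correlation and 0 with fry, and ran from 4 (without C3-E6) to 10 (without C8-E7) with 1 pair left out, 5 without C4-E3. In skeletal muscle 15 lists were called, 3 with an estimated correlation, 0 with fry, and 12 without each pair in turn. For the difference 7 were called, 13 with median centring, 11 with outlier spots kept, 4 without the discordant muscle array and 1 with an estimated correlation, and 5 (without C4-E3) to 11 (without C8-E7) with 1 pair left out. A larger correlation widens the null of a list, and the causes of the other changes were not tested. Of 29 called lists reported, lipid synthesis for the difference kept its call in every alternative run for it, and lipid synthesis and slow-fibre genes in skeletal muscle in every one but fry. fry was run for heart and skeletal muscle only, where it called 0 lists.

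The agreement of heart and skeletal muscle, a correlation of 0.171, was -0.2 with median centring, and ran from -0.15 (without C3-E6) to 0.18 (without C8-E7). Median centring moved the median of all genes for the difference to 0.121 from 0.02. Medians of lists also turned. That of complex I subunits, difference, was 0.23 with median centring. That of fast muscle fibre genes, skeletal muscle, was -0.079 with only KIKO in Cy5, -0.03 without the discordant muscle array (adjusted p = 0.351) and from 0.0016 (without C3-E6) to 0.32 (without C4-E3) with 1 pair left out. The direction of its test turned with only KIKO in Cy5 and without C3-E6. That of glycolysis and glycogen, skeletal muscle, ran from -0.019 (without C3-E6) to 0.23 (without C4-E3). That of the citric acid cycle, skeletal muscle, was -0.049 with only KIKO in Cy3. The causes were not tested.

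Of the named genes, 117 of 137 values had the same sign in every alternative, and 32 of 3392 values had the opposite sign. Slc25a4, heart, turned to 0.13 with only KIKO in Cy3; its spots were saturated on most heart arrays, and the cause was not tested. Signal over background limits the weakest probes: between 63.14% and 89.61% of probes were well above background in a channel. In the channel with the highest share, 85.19% of negative-control spots were flagged too.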

Other observations

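The genes of the next paragraph and the correlations between arrays and pairs were chosen after their values were seen, while the tests of lists and sex genes were planned.

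Some genes had opposite signs in the 2 tissues at an unadjusted p under 0.05 in each, and none passed for the difference. The mitochondrially encoded cytochrome b, mt-Cytb, had a log2 KIKO/WT of -0.233 in heart and 0.257 in skeletal muscle, the folate enzyme Ftcd -0.227 and 0.223, and the glycogen-targeting subunit Ppp1r3b -0.199 (n = 2) and 0.188 (limma, n = 3 otherwise). The other way went the proton pump subunit Atp6v0a1 (0.234 and -0.201) and the forkhead factor Foxq1 (0.378, n = 2, and -0.301). Among transcripts lower in both tissues were the peroxisome proliferator-responsive thioesterase Acot1 (-0.246 and -0.247), the macrophage gene Aif1 (-0.213 and -0.17) and the tumour suppressor Flcn (-0.234 and -0.147). None passed the test over all genes.

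The remaining lists were not called. In heart and skeletal muscle, medians were 0.00153 and -0.0143 for muscle atrophy and regeneration (camera adjusted p = 0.882 and 0.595), -0.00513 and 0.00534 for the circadian clock (0.879 and 0.986), -0.0102 and -0.0257 for endothelial markers (0.879 and 0.717), 0.0149 and 0.00324 for Schwann cell and nerve markers (0.559 and 0.986) and -0.0344 and -0.0108 for atrial and conduction markers (0.443 and 0.418). Lists called in 1 tissue had in heart medians of 0.0249 for lipid synthesis (0.765), 0.0639 for mitochondrial biogenesis (0.0881), -0.0104 for cardiac stress (0.879), -8.12e-05 for extracellular matrix (0.879), -0.0125 for slow-fibre genes (0.306), -0.0126 for immune cells (0.443), -0.0177 for chaperones (0.133), -0.0349 for red blood cells (0.879) and -0.0384 for ventricular genes (0.879). In skeletal muscle immediate early genes had -0.0801 (0.157) and smooth muscle genes -0.0765 (0.318). White adipocyte markers had -0.0208 in heart (0.186).

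The sex genes had log2 KIKO/WT values of 0.08 and 0.02 for Ddx3y, 0.03 and 0.07 for Eif2s3y and -0.02 and -0.04 for Kdm5d in heart and skeletal muscle, and -0.13 for Xist in skeletal muscle.

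The log2 KIKO/WT values of heart in C4-E3 and skeletal muscle in C3-E6 had the highest correlation across probes among all 15 pairings of tissue and mouse pair, 0.379, while skeletal muscle of C3-E6 and C4-E3 had the lowest, -0.413. Dye-swapped arrays of a pair had correlations across bright probes of 0.511, 0.393 and 0.513 in heart and 0.851, -0.201 and 0.624 in skeletal muscle for C3-E6, C4-E3 and C8-E7, and across all probes of 0.177, -0.0327 and 0.479 and of 0.844, -0.195 and 0.441. Whether the dyes and labels of the C4-E3 muscle arrays are as given was not tested, and each muscle value of this pair rests on them. Negative controls were well above background for 85.19% of spots in Cy3 on the heart array of C3-E6 with KIKO in Cy3.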
